A study of Sus scrofa with 10 samples.

How the data were processed

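Nuclear RNA of sorted cardiomyocytes from minipig (Sus scrofa) hearts had been sequenced in 10 libraries. Per the labels, 5 libraries formed the control group, which received phosphate-buffered saline, 2 formed the group of deoxycorticosterone acetate (DOCA), and JK07 was added to DOCA in the last 3. The heart chamber, the doses and the times were not given in the sources used here. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the TruSeq RNA kit. Labels gave each library its own number from 1 to 10, and no number was shared between groups. The labels thus gave no pairing, though running numbers cannot exclude one. They did not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

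Per the submitters' processing notes, SAMtools, StringTie and edgeR were used on the genome build Sscrofa11.1. The aligner, the tool versions and the annotation release were not given in the sources used here. Per the file headers, each library had a gene abundance table with the coverage signal, FPKM and TPM of 35670 gene identifiers. The authors also deposited a table of whole-number estimated counts with 1 column per library and no gene column. That table had 35670 lines. Sorting the identifiers made 99.998% of values 0 in both tables or in neither, against 62.6% when the identifiers were moved by 1 line. Across the 13476 genes above 0 in at least 8 libraries, the median correlation of the count and coverage profiles of the same identifier was 1.00, and 98.9% of them exceeded 0.9, against 10.7% with a random identifier. The zero patterns differed in 6 values of 1 gene. All 10 count columns were closest to the coverage of their own library.

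The deposited counts were not directly counted reads. For genes spanning under 1000 bp, 80.9% of 11109 values lay within 0.5 counts of coverage multiplied by length and divided by 75, so they were treated as estimated counts derived from coverage. They were whole numbers as deposited, so rounding to whole numbers moved none of them. In each library the smallest TPM above 0 corresponded to a coverage of 1.00, and 3.96% of coverage values above 0 lay under 1. A gene listed at 0 therefore lay under a coverage minimum that weighs more at low depth, and its fold change was not read as a size. The deposited FPKM values entered no test. The authors' counting of strand was not given in the sources used here, so overlapping and antisense genes, and families with near-identical copies such as ribosomal proteins and histones, are uncertain.

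Gene symbols came from the files for 23878 identifiers and from a reference table for 109 more, and 11683 had none. Of 15514 identifiers named in both, 15441 had the same symbol. A list member was matched to the identifier of that symbol with the highest mean count. Coordinates are 1-based, on Sscrofa11.1, as the files give them.

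The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter and group as the only term. All 10 libraries entered 1 model, so that the 3 groups shared the estimate of spread. With 2 libraries, the DOCA group added little to that estimate, so p-values of its comparisons rest mainly on the spread of the other groups. The DOCA libraries were less alike (mean correlation 0.738, against 0.810 between controls and 0.798 between JK07 libraries), so these p-values may be too small. Quality weights per library, which let the spread differ, gave 161 genes for DOCA against control instead of 4391. For DOCA plus JK07 against DOCA they gave 5 instead of 2930. The biological coefficient of variation was 0.873 over 17251 genes, and the median prior degrees of freedom were 2.03. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, separately for DOCA against control, DOCA plus JK07 against DOCA and DOCA plus JK07 against control. CPM values were computed from the total count of a library after TMM scaling, and errors are SD over libraries for CPM. For log2 fold changes in edgeR they are approximate standard errors (SE), the absolute log2 fold change divided by the square root of its F statistic.

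There were 36 gene lists: 22 of cardiac function, 9 of other cell types, 2 of heart chambers and 3 named here after RNA quality. No RNA integrity value was given in the sources used here, so that these 3 follow it was not tested. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, which compares a list with all other genes, and adjusted over the 108 tests of the 3 comparisons. Camera with a correlation estimated per list and fry, which tests whether a list's genes move one way on balance, stood beside it. With an estimated correlation the lowest adjusted p of all 108 tests was 0.982, so no camera call held. Where counts of changed members are given, they are over all genes tested, and those adjusted over the list alone are given where they differ or named as the same.

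The groups, the tests, the gene lists, the rule for named genes and most of the other settings tried were fixed before the data were examined. Per comparison, the rule took genes with a symbol past the threshold, with non-overlapping CPM ranges in the compared groups and a mean of at least 5 CPM, and named the 5 with the largest increase and the 5 with the largest decrease. Where fewer passed, the direction was filled up to 3 by the smallest p. It added up to 3 members with the smallest p from each of the 8 lists with the most changed members (at least 2), up to 2 members of each cell type, chamber and RNA quality list, and a panel of 8 genes whatever their p: ERBB4, ERBB2, ERBB3, NRG1, NPPA, NPPB, NR3C2 and FKBP5. Any other gene named was chosen after its values were seen. Some genes that the rule selected are not reported here.

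Those settings were RLE and upper quartile scaling, DESeq2 1.42.0, limma voom with quality weights per library, limma on log2(TPM + 1) and log2(TPM + 0.1), no filter, at least 1 CPM in 5 libraries, only the 2 compared groups, mitochondrial genes left out, stricter thresholds and each library left out in turn. When a DOCA library was left out, the lone library was assumed to vary like the other groups. The following were chosen after seeing the data. The 17 genes of ribosomal RNA scaffolds were left out. The test was restricted to genes with a mean of at least 100 CPM of the counts outside those scaffolds and the 37 mitochondrial genes. Every library was thinned to 3.30 M (mega) counts outside the scaffolds, with values under a coverage of 1 then set to 0. Voom with quality weights was also run on the control and DOCA plus JK07 groups alone.

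The procedure was tested on simulated counts of the real genes with 200 genes changed, 100 by 2-fold and 100 by 4-fold. With the coverage minimum applied, DOCA against control (15394 genes) recovered 8 and 35 of them, and called 163 unchanged genes, of which 158 had a group at 0. DOCA plus JK07 against DOCA (15468 genes) recovered 3 and 24, and called 182 unchanged genes, of which 180 had a group at 0. DOCA plus JK07 against control (15458 genes) recovered 4 and 33, and called 2 unchanged genes. Without the minimum, DOCA against control (16336 genes) recovered 0 and 21 and called 4 unchanged genes, DOCA plus JK07 against DOCA (16341 genes) recovered 0 and 0 and called none, and DOCA plus JK07 against control (16347 genes) recovered 4 and 45 and called 4 unchanged genes. For the lists, the sarcomere and Z disc genes were also raised 2-fold. Besides that list, camera called 1 other in DOCA plus JK07 against DOCA, with and without the minimum, and 0 in the other comparisons. Some of the other lists share genes with the raised list. Genes were drawn independently of each other, so the simulation cannot show how many lists camera calls wrongly where genes are correlated. Because most false gene calls with the minimum had a group at 0, genes measured above 0 in both groups are described first.

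Comparisons that share libraries were set beside simulations: 20 of unchanged groups against the same controls, 20 splits of the controls, and 10 each in which the JK07 group equalled DOCA or control. No pair of libraries looked like copies: over 45 pairs the highest share of identical values was 1.05% and the highest correlation of log2(count + 1) was 0.831. No genome sequence was used here, so base composition was not computed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used.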

Results

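The libraries measured nuclear RNA, which is rich in unprocessed transcripts, from cardiomyocytes sorted from minipig hearts. DOCA is a precursor-type corticosteroid that acts on the mineralocorticoid receptor and is used to raise blood pressure in animals, and JK07 is named in the series title as an agonist of ERBB4, the neuregulin receptor of cardiomyocytes. The series concerns atrial remodeling and the inducibility of atrial fibrillation. The control group had 5 libraries (1 to 5), DOCA had 2 (6 and 7) and DOCA plus JK07 had 3 (8 to 10).

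Total estimated counts ran from 28.1 to 106 M (M, mega) per library, of which 77.6% to 90.8% lay on ribosomal RNA scaffolds. Outside these scaffolds and the mitochondrial genome, DOCA library 6 held 6.87 M counts and library 7 held 3.30 M, against 8.67 to 13.9 M in the 5 controls and 9.03 to 12.9 M in the 3 JK07 libraries. Of 12530 expressed genes, 21.05% and 24.5% were listed at 0 in libraries 6 and 7, and 0.718% to 3.71% in the other 8. Thinned to 3.30 M counts, library 6 had 39.7% at 0, library 7 had 24.5%, and the others had 17.9% to 22.9%. Mitochondrial genes took 2.58% and 0.488% of counts outside the scaffolds in libraries 6 and 7, against 3.69% to 8.26% elsewhere. The first principal component (44.8% of variance) parted libraries 6 and 7 from all others. On the second (14.7%) these libraries lay at opposite ends, at 192 and -161. The mean correlation was 0.810 between controls, 0.650 between control and DOCA, and 0.797 between control and DOCA plus JK07. It was 0.738 between the DOCA libraries and 0.798 between the JK07 libraries, so the DOCA libraries were less alike than those of either other group. The DOCA group thus consisted of the 2 libraries with the fewest counts outside the scaffolds and the most genes at 0, and every value of that group below stands beside these measures.

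**Figure D1:**
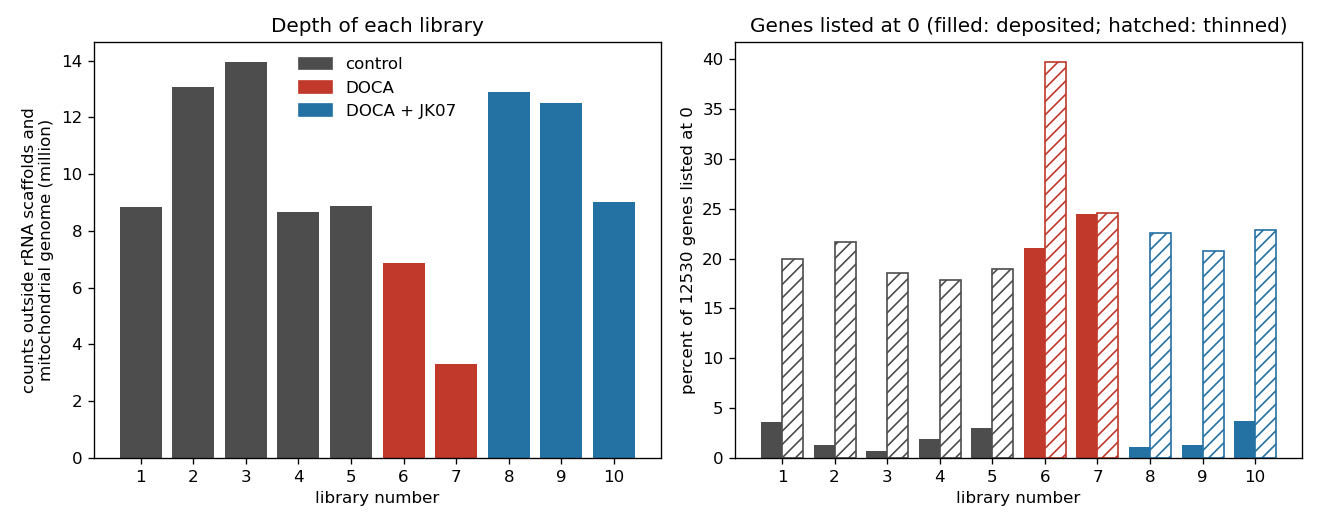
Left bars give, for each of the 10 libraries, the estimated counts outside ribosomal RNA scaffolds and the mitochondrial genome in M (mega), and right bars give the percent of 12530 expressed genes listed at 0, as deposited (filled) and after thinning to 3.30 M counts (hatched). DOCA libraries 6 and 7 have 6.87 and 3.30 M counts and 21.05% and 24.5% of genes at 0, against at most 3.71% in the other libraries.

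The comparison of DOCA with control asked how cardiomyocyte transcripts differed after DOCA alone. Part of the genes of mitochondrial energy supply fell, 22 of 47 for oxidative phosphorylation and 11 of 25 for the tricarboxylic acid cycle. Beside them fell 13 of 13 mitochondrially encoded and 27 of 46 ribosomal protein genes, of the lists named after RNA quality. None of these list calls held with an estimated correlation. Over all genes tested 3403 of 17251 were lower, and counts of lower list members are to be read against that share. CS, citrate synthase at the entry of the tricarboxylic acid cycle, went from 26.5 ± 4.67 CPM (SD, n = 5) in control to 9.73 ± 0.280 CPM (SD, n = 2) in DOCA. DECR1, an enzyme of unsaturated fatty acid oxidation, went from 9.57 ± 1.46 to 1.55 ± 0.446 CPM, and PLN, phospholamban, the brake of the calcium pump of the sarcoplasmic reticulum, from 16.6 ± 5.65 to 1.60 ± 0.417 CPM. TNFRSF12A, the receptor of the cytokine TWEAK, rose from 1.84 ± 1.16 to 22.7 ± 11.4 CPM. NPPA, the atrial natriuretic peptide gene, stood at 456 ± 59.7 CPM in control and 464 ± 9.57 in DOCA and did not pass the test.

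Among 47 measured nuclear genes of oxidative phosphorylation, which supplies most ATP of the heart, 22 fell and 0 rose over all genes tested, and 27 fell adjusted over the list alone. The median log2 change was -1.27. Examples are COX6C, a cytochrome c oxidase subunit, with a log2 change of -2.23 (SE 0.31, adjusted p = 0.000587), NDUFA4, also of that complex, at -2.21 (SE 0.32, adjusted p = 0.000826) and the ATP synthase gene ATP5PB at -1.80 (SE 0.26, adjusted p = 0.000887). Of 25 tricarboxylic acid cycle genes 11 fell and 0 rose over all genes tested, and adjusted over the list alone 14 fell and 1 rose (median -0.93). CS (ENSSSCG00000035686, chromosome 5, 21666585 to 21700711) changed by -1.45 (SE 0.21, adjusted p = 0.000726), SUCLA2, a succinyl-CoA synthetase subunit, by -1.92 (SE 0.34, adjusted p = 0.00305) and MDH1, a malate dehydrogenase, by -2.44 (SE 0.45, adjusted p = 0.00337; -3.19 without library 7). Camera called both lists lower, with adjusted p = 0.000255 and 0.00285. With an estimated correlation the unadjusted p was 0.308 for oxidative phosphorylation and 0.247 for the cycle. Under upper quartile scaling 16 genes of oxidative phosphorylation fell and 0 rose, and 6 of the cycle fell and 1 rose.

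Genes of the lists named after RNA quality moved with these lists. All 13 measured genes encoded by the mitochondrial genome fell (median -2.93, camera adjusted p = 1.43e-05, p = 0.168 with an estimated correlation), over all genes and adjusted over the list alone. COX2, the mitochondrially encoded cytochrome c oxidase subunit, went from 49.9 ± 17.1 CPM (SD, n = 5) to 4.57 ± 2.01 CPM (SD, n = 2), a log2 change of -3.45 (SE 0.54, adjusted p = 0.00125), and ND4L of complex I changed by -2.65 (SE 0.44, adjusted p = 0.00179). Of 46 ribosomal protein genes 27 fell and 0 rose, and 30 fell adjusted over the list alone (median -1.04, camera adjusted p = 0.000185, p = 0.252 with an estimated correlation), with RPL14 at -2.31 (SE 0.23, adjusted p = 7.84e-05) and RPL23 at -1.46 (SE 0.17, adjusted p = 0.000216). Under upper quartile scaling all 13 mitochondrially encoded genes still fell, and 22 ribosomal protein genes fell and 1 rose. Of 7 histone genes 3 fell, and 5 adjusted over the list alone (camera adjusted p = 0.0965); H2BC21 and H2BC5 were listed at 0 in both DOCA libraries.

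Fatty acid uptake and oxidation had 7 members that fell and 2 that rose of 32 measured (8 and 2 adjusted over the list alone; camera adjusted p = 0.869). DECR1 changed by -2.62 (SE 0.26, adjusted p = 8.47e-05), ETFA, which carries electrons from acyl-CoA dehydrogenases, by -2.33 (SE 0.28, adjusted p = 0.000230) and the dehydrogenase ACADL by -1.42 (SE 0.27, adjusted p = 0.00426). Calcium handling had 5 members that fell and 0 that rose of 24 (7 and 2 adjusted over the list alone; camera adjusted p = 0.618). PLN (ENSSSCG00000062089, chromosome 1, 43449354 to 43458925) changed by -3.37 (SE 0.45, adjusted p = 0.000471). Of 38 genes near atrial fibrillation risk loci, of which PLN is 1, 8 fell and 2 rose over all genes and adjusted over the list alone (camera adjusted p = 0.775). KCND3, the channel of the transient outward potassium current, and KCNN3, a small-conductance calcium-activated potassium channel, were listed at 0 in both DOCA libraries, with control means of 3.08 ± 0.541 and 3.10 ± 1.23 CPM (SD, n = 5). Ion channels and transporters of the action potential had 7 members lower and 1 higher of 31, over all genes and adjusted over the list alone (camera adjusted p = 0.824). In each list of this paragraph the share of lower members lay close to that over all genes tested, 3403 of 17251.

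Among 28 cardiac transcription factors 6 fell and 0 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.817). That share of lower members also lay close to the share over all genes tested. TBX5, a regulator of atrial rhythm genes, went from 14.8 ± 4.46 to 2.58 ± 0.765 CPM (log2 change -2.52, SE 0.60, adjusted p = 0.0149), and without library 7 it changed by -2.25 with adjusted p = 0.0793. Sarcomere and Z disc genes went both ways, with 4 lower and 2 higher of 25 over all genes and adjusted over the list alone (camera adjusted p = 0.824). Chosen after their values were seen, MYOZ2, a Z disc protein that binds calcineurin, changed by -2.31 (SE 0.33, adjusted p = 0.000729), while FLNC, filamin C of the Z disc, changed by 3.12 (SE 0.55, adjusted p = 0.00286). Library 6 carried much of the FLNC change: without it FLNC changed by 1.69 (adjusted p = 0.0448), and without library 7 by 3.81. Natriuretic peptides and fetal-type cardiac genes had 2 members higher and 1 lower of 22 (1 and 1 adjusted over the list alone; camera adjusted p = 0.111). NPPB, the B-type natriuretic peptide gene, stood at 14.8 ± 10.6 CPM in control and 29.4 ± 8.74 in DOCA (log2 change 0.99, SE 0.69, adjusted p = 0.319).

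Of the genes that rose most, TNFRSF12A (ENSSSCG00000027130, chromosome 3, 39166298 to 39168302) changed by 3.63 (SE 0.65, adjusted p = 0.00296) and by 2.99 without library 6. EEIG1 (ENSSSCG00000005631, chromosome 1, 268427708 to 268465786), a gene known from estrogen induction, went from 4.91 ± 1.19 to 55.4 ± 53.7 CPM (log2 change 3.50, SE 0.54, adjusted p = 0.00123). Without library 6 it changed by 1.83 (adjusted p = 0.0141) and without library 7 by 4.25. TRIM54, a muscle ubiquitin ligase (chromosome 3, 111834181 to 111852744), had 126 CPM in library 6 and 9.17 CPM in library 7, against 5.97 ± 1.60 CPM in control (log2 change 3.50, SE 0.75, adjusted p = 0.00845), and without library 6 it changed by 0.62 with adjusted p = 0.481, and without library 7 by 4.39. HABP2, an extracellular serine protease (3.94, SE 1.20, adjusted p = 0.0417) and the ERK phosphatase DUSP5 (3.91, SE 1.24, adjusted p = 0.0476) lay near the threshold. HABP2 lost the call without any 1 control library (adjusted p = 0.0650 to 0.0830) and without library 6 (2.49, adjusted p = 0.257), and DUSP5 without library 6 changed by 2.33 (adjusted p = 0.312). Without library 7 they changed by 4.65 and 4.64. DUSP5 also lost it without any 1 control (adjusted p = 0.0678 to 0.0992), without library 8 (adjusted p = 0.0652) and without library 9 (adjusted p = 0.0683).

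**Figure D2:**
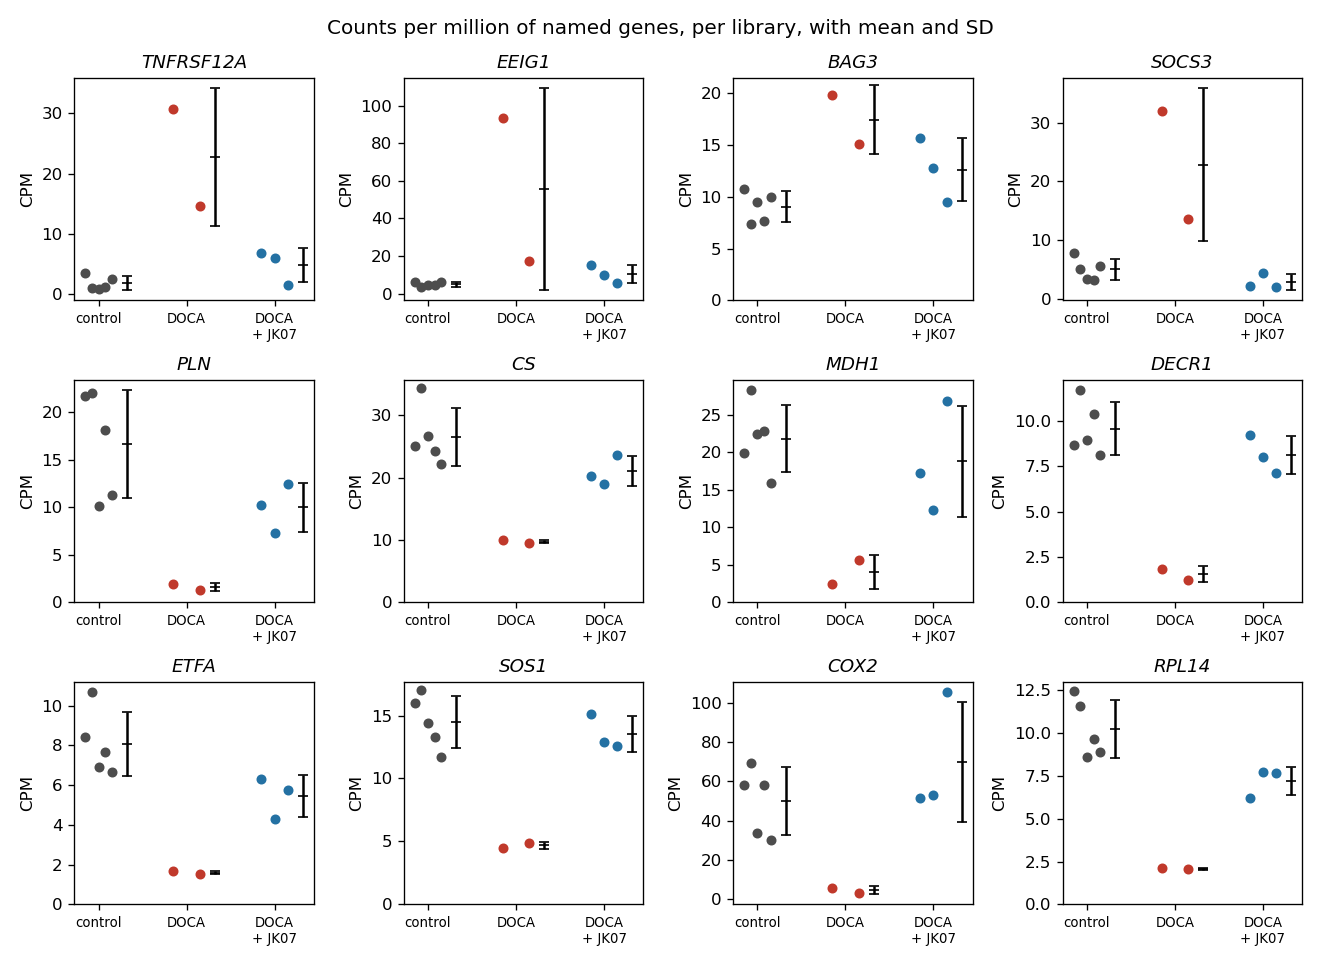
Each panel shows CPM of 1 gene per library, with the mean and SD of the 5 control, 2 DOCA and 3 DOCA plus JK07 libraries, for 12 genes named in the text. PLN, CS, MDH1, DECR1, ETFA, SOS1, the mitochondrially encoded COX2 and RPL14 are lowest in DOCA, while TNFRSF12A, EEIG1, BAG3 and SOCS3 have their highest mean there.

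ERBB receptors, ligands and downstream genes went both ways, with 3 higher and 5 lower of 22 (4 and 5 adjusted over the list alone; camera adjusted p = 0.618). SOS1, the exchange factor that couples receptor kinases to Ras, went from 14.5 ± 2.10 to 4.70 ± 0.268 CPM (log2 change -1.63, SE 0.20, adjusted p = 0.000265). NRG4, an ERBB4 ligand, and PIK3CB, a catalytic subunit of PI3-kinase, were listed at 0 in both DOCA libraries, with control means of 3.48 ± 0.302 and 5.51 ± 1.22 CPM. ERBB4 itself (ENSSSCG00000016160, chromosome 15, 113974437 to 115096565) stood at 51.4 ± 17.0 CPM (SD, n = 5) in control and 27.1 ± 10.4 CPM (SD, n = 2) in DOCA, a log2 change of -0.92 (SE 0.42, adjusted p = 0.148) that did not pass in edgeR. It passed in limma on log2(TPM + 1) (-1.33, adjusted p = 0.0299) and log2(TPM + 0.1) (-1.44, adjusted p = 0.0269). Nearly all genes called in these models were lower: 4933 against 258 higher in the former, and 5681 against 221 in the latter. A pass there was therefore not particular to ERBB4. ERBB2, its partner receptor, (0.43, SE 0.36, adjusted p = 0.389) and NRG1, neuregulin 1, (1.00, SE 0.85, adjusted p = 0.403) did not pass, and NRG1 stood at 1.67 without library 6 and -0.30 without library 7. ERBB3 was at 0 in library 6 and at 9.57 CPM in library 7 (adjusted p = 0.605), and without library 6 its adjusted p was 0.0476 at a log2 change of 1.96. NR3C2, the mineralocorticoid receptor gene, changed by -0.65 (SE 0.29, adjusted p = 0.145) and passed only without library 7 (-1.18, adjusted p = 0.0242). FKBP5, a glucocorticoid-induced chaperone gene, changed by -0.52 (SE 0.56, adjusted p = 0.513). Of 27 corticosteroid response genes 2 rose and 3 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.252).

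Of 41 extracellular matrix and fibrosis genes 4 rose and 1 fell (4 and 0 adjusted over the list alone), and camera called the list higher (adjusted p = 0.00327), though without library 7 the adjusted p was 0.929. With an estimated correlation p = 0.404. Named after its values were seen, TIMP1, an inhibitor of matrix metalloproteinases, changed by 2.34 (SE 0.40, adjusted p = 0.00236). Of 29 interferon response genes 13 fell and 0 rose, and 14 fell adjusted over the list alone. The median was -1.75, and -1.04 with members at 0 in a whole group placed at the coverage minimum. The antiviral genes IFIT5, IFIH1 and IFIT1 were listed at 0 in both DOCA libraries, with control means of 3.41, 6.54 and 2.19 CPM. Camera called the interferon list lower (adjusted p = 0.0326; 0.223 without library 6), with p = 0.396 with an estimated correlation. Inflammation and NF-kB genes had 2 members higher and 4 lower of 29 (2 and 2 adjusted over the list alone; camera adjusted p = 0.206). Growth factor immediate early genes had 2 and 2 of 34 (0 and 1 adjusted over the list alone; camera adjusted p = 0.0504).

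Of 18 circadian clock genes 3 rose and 6 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.934). NR1D2, a nuclear receptor that represses BMAL1, went from 13.7 ± 1.22 to 2.83 ± 0.593 CPM (log2 change -2.28, SE 0.23, adjusted p = 8.34e-05), and BHLHE41 and DBP were listed at 0 in both DOCA libraries. Unfolded protein and heat shock genes had 3 members higher and 6 lower of 29, over all genes and adjusted over the list alone (camera adjusted p = 0.868). BAG3, a co-chaperone of the Z disc, went from 9.06 ± 1.49 to 17.5 ± 3.30 CPM (log2 change 0.95, SE 0.23, adjusted p = 0.0163; 0.107 without library 6), SEL1L of endoplasmic reticulum degradation changed by -1.36 (SE 0.28, adjusted p = 0.00724), and ASNS, asparagine synthetase, was listed at 0 in both. The genes with the largest fitted falls, QSER1, SLF2, HYCC2, NECTIN3 and OGFRL1, had control means of 11.2 to 16.1 CPM and were all listed at 0 in both DOCA libraries, so no fold was read.

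Markers of other cell types also moved. Of 18 fibroblast genes 2 fell (1 adjusted over the list alone): ABCA8, a lipid transporter gene, went from 37.8 ± 7.52 to 7.41 ± 3.24 CPM (log2 change -2.35, SE 0.39, adjusted p = 0.00184), and its neighbour ABCA9 changed by -2.07 (SE 0.58, adjusted p = 0.0307). ABCA9 lost the call without library 1, 3, 4, 6 or 8 (adjusted p = 0.0573, 0.0553, 0.0661, 0.104 and 0.0512), and without library 7 it changed by -3.36. Of 18 macrophage and monocyte genes 3 fell (2 adjusted over the list alone), with RBPJ, the Notch-pathway transcription factor, at -1.59 (SE 0.36, adjusted p = 0.0118; 0.0608 without library 7) and LYVE1 listed at 0 in both (adjusted p = 0.0878 without library 6 and 0.0707 without library 7). Of 24 endothelial genes 2 rose and 4 fell, CALCRL and ADGRL4 at 0 in both, and of 16 smooth muscle and pericyte genes 4 fell, AGTR1 and ITGA8 at 0 in both. Lymphocyte genes had 1 lower of 9 (CD247 at 0 in both), Schwann cell and neuron genes 2 lower of 9 (MBP and SCN7A at 0 in both, SCN7A past the threshold with adjusted p = 0.0413 but not without any 1 library other than 5), and adipocyte genes 1 higher and 3 lower of 13 (SCD and GPAM at 0 in both). HAS1, a hyaluronan synthase, was the only member past the threshold of 9 mesothelial genes (log2 change 1.93, SE 0.38, adjusted p = 0.00567; 0.0843 without library 6), and 0 of 3 erythrocyte genes passed in edgeR. Atrial cardiomyocyte genes had 1 higher and 2 lower of 17, with NR2F1 at 0 in both, and ventricular genes had 1 lower of 13: MYL3, the ventricular essential light chain, at -1.89 (SE 0.47, adjusted p = 0.0170; 0.0918 without library 7). For all lists named here from endothelial to ventricular genes, counts adjusted over the list alone were the same. Camera adjusted p-values of the 9 cell type lists ran from 0.168 to 0.934, and those of the atrial and ventricular lists were 0.996 and 0.319.

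**Figure D3:**
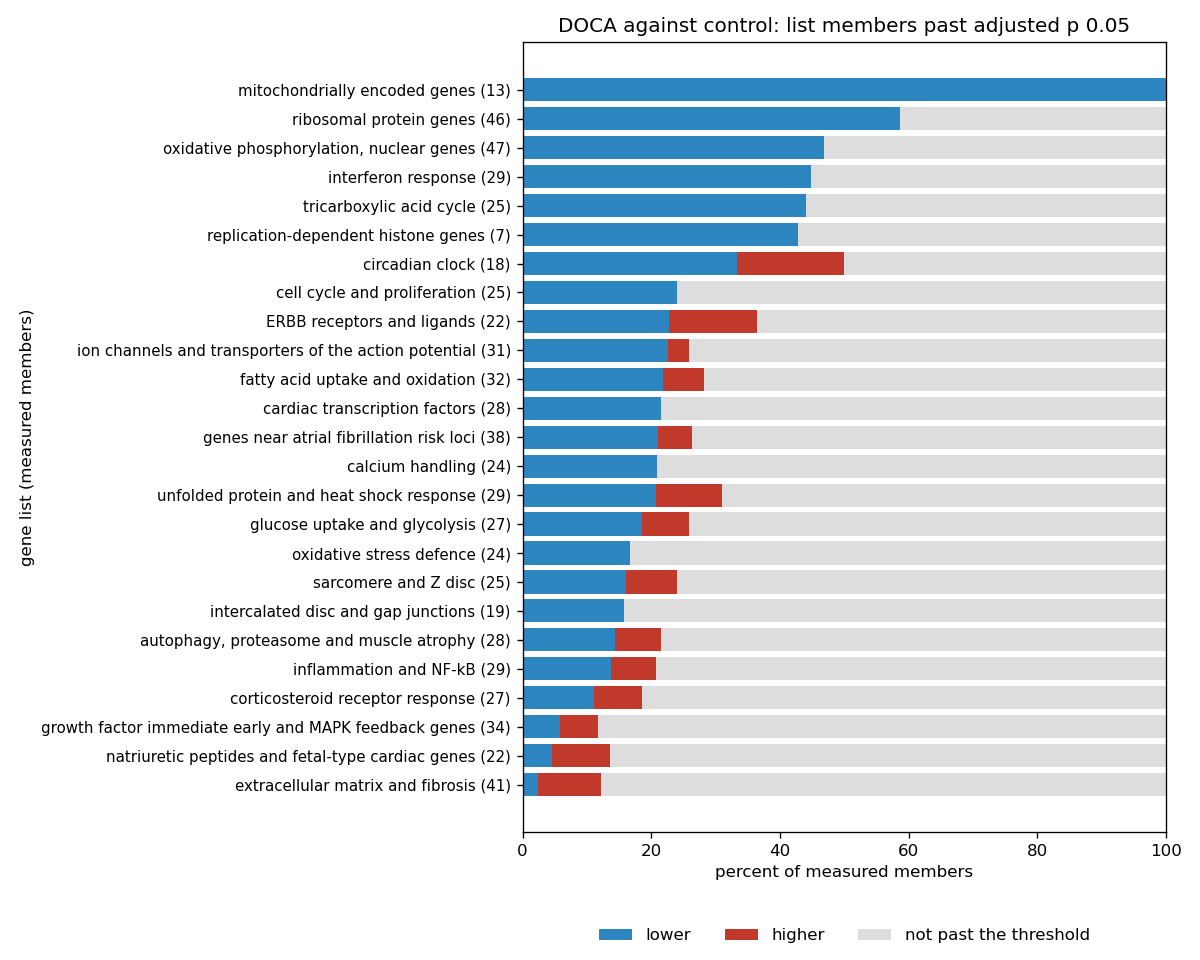
Bars give, for the 22 function and 3 RNA quality lists, the percent of measured members lower, higher or not past the threshold in DOCA against control (edgeR, adjusted p of 0.05 over all genes). All 13 mitochondrially encoded genes, 27 of 46 ribosomal protein genes and 22 of 47 genes of oxidative phosphorylation are lower, and members of the sarcomere and circadian lists lie on both sides.

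Over all 17251 genes tested, 4391 passed the threshold in DOCA against control, 988 higher and 3403 lower. Of the lower genes, 2030 were listed at 0 in both DOCA libraries. Leaving out the 2045 called genes with a whole group at 0, 973 were higher and 1373 lower. The scaling set part of that balance: the median log2 change of all genes was -0.63 with TMM, -0.56 with RLE and -0.39 with upper quartile factors, which gave 1523 higher and 2868 lower genes. Limma on log2(TPM + 1), which differs in measure and test as well, gave 258 higher and 4933 lower. The median, mean and camera direction of a list differed in sign for the natriuretic, sarcomere, ERBB, immediate early, corticosteroid, inflammation, glycolysis, autophagy, endothelial, smooth muscle, adipocyte and atrial lists. With quality weights per library in limma voom, 161 genes passed (67 higher, 94 lower), 158 of them called the same way by edgeR, and 5 of the 57 named genes past the threshold kept their call: CS, EEIG1, NR1D2, QSER1 and TNFRSF12A. With all libraries thinned to 3.30 M counts 1881 passed (644 higher, 1237 lower), and among genes of at least 100 CPM 675 of 1809 passed (322 higher, 353 lower). After thinning 30 of the 47 named genes that could be tested kept their call, and COX6C, SUCLA2, NR1D2 and SEL1L were not among them.

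The comparison of DOCA plus JK07 with DOCA asked how transcripts differed when JK07 was added. Some genes that were low in DOCA were higher with JK07, among them 11 of 47 for oxidative phosphorylation, 5 of 24 for calcium handling and 5 of 28 cardiac transcription factors, and most members of these lists did not pass. Over all genes tested 2542 of 17251 were higher, and the 5 of 28 lay close to that share. Other counts of higher list members are to be read against it as well. DECR1 stood at 8.13 ± 1.07 CPM (SD, n = 3) with JK07 and 1.55 ± 0.446 (SD, n = 2) in DOCA, PLN at 9.99 ± 2.59 and 1.60 ± 0.417, and LPL, the lipase that releases fatty acids from lipoproteins, at 25.5 ± 10.98 and 2.89 ± 1.86. The genes SOCS3 and ERRFI1 were lower with JK07: SOCS3, which restrains cytokine signalling through STAT3, stood at 2.81 ± 1.39 CPM with JK07 and 22.8 ± 13.04 in DOCA, and ERRFI1, which inhibits ERBB kinases, at 4.28 ± 2.66 and 27.3 ± 8.06. ERBB4 stood at 44.5 ± 16.1 CPM with JK07 and 27.1 ± 10.4 in DOCA and did not pass in edgeR.

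SOCS3 (ENSSSCG00000036956, chromosome 12, 3643929 to 3647009) changed by -3.02 (SE 0.53, adjusted p = 0.00308) and by -2.27 without library 6. ERRFI1 changed by -2.67 (SE 0.55, adjusted p = 0.00803) and by -3.28 without library 9. TEAD4, a transcription factor of the Hippo pathway (-2.89, SE 0.65, adjusted p = 0.0134), lost the call without library 6 (-1.14, adjusted p = 0.150) and library 8 (adjusted p = 0.0525), and without library 7 it changed by -3.66. DHODH, an enzyme of pyrimidine synthesis (-2.90, SE 0.82, adjusted p = 0.0398), lost it without library 2, 3, 7, 8, 9 or 10 (adjusted p = 0.0514, 0.0637, 0.157, 0.0978, 0.0589 and 0.0870), changing by -2.03 without library 7. SPECC1 (-2.43, SE 0.67, adjusted p = 0.0352) lost it without library 3, 5, 6, 8, 9 or 10 (adjusted p = 0.0577, 0.0540, 0.167, 0.0732, 0.0511 and 0.0538) and changed by -1.63 without library 6. Camera called the inflammation and NF-kB list lower with JK07 (adjusted p = 0.000308, p = 0.0830 with an estimated correlation), with 3 members lower and 1 higher of 29, over all genes and adjusted over the list alone. It also called extracellular matrix and fibrosis lower (adjusted p = 0.0256, p = 0.487 with an estimated correlation; 3 lower and 1 higher of 41, 2 and 1 adjusted over the list alone) and growth factor immediate early genes (adjusted p = 0.0371, p = 0.345 with an estimated correlation; 1 higher and 0 lower of 34, both ways of adjusting). The matrix list lost its call without library 7 (adjusted p = 0.851, higher) and library 10 (0.353), and the immediate early list without library 6, 7, 8 or 10 (0.0594, 0.247, 0.201 and 0.116).

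Of 47 genes of oxidative phosphorylation 11 were higher and 0 lower with JK07 (12 and 0 adjusted over the list alone; camera adjusted p = 0.200). COX6C changed by 1.73 (SE 0.31, adjusted p = 0.00370), NDUFS3 of complex I by 1.52 (SE 0.31, adjusted p = 0.00799) and COX7B by 1.64 (SE 0.34, adjusted p = 0.00887). Of 32 fatty acid genes 7 were higher and 1 lower, over all genes and adjusted over the list alone (camera adjusted p = 0.522). DECR1 changed by 2.38 (SE 0.27, adjusted p = 0.000187), ETFA by 1.77 (SE 0.28, adjusted p = 0.00160) and LPL by 3.14 (SE 0.55, adjusted p = 0.00307; 4.02 without library 6). The tricarboxylic acid cycle had 4 higher and 0 lower of 25 (5 and 0 adjusted over the list alone; camera adjusted p = 0.0607). All 13 mitochondrially encoded genes were higher (median 3.51, camera adjusted p = 1.67e-07, p = 0.0901 with an estimated correlation), over all genes and adjusted over the list alone. COX2 changed by 3.93 (SE 0.57, adjusted p = 0.000838) and ND1 by 4.15 (SE 0.64, adjusted p = 0.00134; 4.94 without library 6). Of 46 ribosomal protein genes 8 were higher and 0 lower, both ways of adjusting (camera adjusted p = 0.484), with RPL14 at 1.80 (SE 0.23, adjusted p = 0.000421) and RPL23 at 1.11 (SE 0.18, adjusted p = 0.00168). Of 7 histone genes 3 were higher (camera adjusted p = 0.176).

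Calcium handling had 5 members higher and 0 lower of 24 with JK07 (8 and 0 adjusted over the list alone; camera adjusted p = 0.361). PLN changed by 2.64 (SE 0.45, adjusted p = 0.00242) and CAMK2G, a calcium-dependent kinase subunit, by 1.40 (SE 0.25, adjusted p = 0.00340). Of 28 cardiac transcription factors 5 were higher and 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 0.571). MEF2A, a myocyte enhancer factor, changed by 1.68 (SE 0.34, adjusted p = 0.00667) and TBX5 by 3.09 (SE 0.65, adjusted p = 0.00879; 2.42 without library 10), and NR2F1, which marks atrial cells, was at 0 in both DOCA libraries and at 0.794 ± 0.302 CPM (SD, n = 3) with JK07. Ion channels had 7 higher and 0 lower of 31 (camera adjusted p = 0.637) and genes near atrial fibrillation loci 7 and 0 of 38 (camera adjusted p = 0.571), both ways of adjusting. KCND3, KCNN3, the channel subunit KCNAB1 and the exchanger SLC9B1 were at 0 in both DOCA libraries and at 2.86, 2.94, 3.97 and 0.976 CPM with JK07. Interferon response had 8 higher and 0 lower of 29 (9 and 0 adjusted over the list alone; camera adjusted p = 0.480), with IFIT5, IFIT1 and IFIH1 at 2.81, 1.71 and 4.19 CPM with JK07.

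ERBB receptors, ligands and downstream genes had 5 members higher and 2 lower of 22 with JK07, over all genes and adjusted over the list alone (camera adjusted p = 0.509). SOS1 changed by 1.53 (SE 0.21, adjusted p = 0.000565), and NRG4 and PIK3CB, at 0 in DOCA, stood at 2.96 ± 0.437 and 4.91 ± 1.45 CPM. Of the panel genes, ERBB4 changed by 0.71 (SE 0.44, adjusted p = 0.310 in edgeR; 0.0435 in limma on log2(TPM + 1) and 0.0411 on log2(TPM + 0.1)), NRG1 by 1.07 (SE 0.99, adjusted p = 0.493; 0.40 without library 6, 2.36 without library 7 and -0.21 without library 9), NPPA by -0.01 (SE 0.24, adjusted p = 1), NPPB by -0.14 (adjusted p = 0.950) and FKBP5 by -0.34 (adjusted p = 0.749; -1.02 without library 8). ERBB2 changed by -0.40 (adjusted p = 0.529) and passed only without library 10 (-0.997, adjusted p = 0.0461). NR3C2 changed by 0.82 (SE 0.32, adjusted p = 0.116) and passed without library 7 (1.35, adjusted p = 0.0190) and in limma on log2(TPM + 1) (1.13, adjusted p = 0.0225) and log2(TPM + 0.1) (1.54, adjusted p = 0.0240). Nearly all genes called in these TPM models were higher with JK07: 5536 against 90 lower on log2(TPM + 1), and 6031 against 53 on log2(TPM + 0.1). A pass there was therefore not particular to ERBB4 or NR3C2. ERBB3 changed by -0.53 (adjusted p = 0.857), and its sign turned without library 7, where the only DOCA library left lists it at 0. Of other cell types, ABCA8 of the fibroblast list was higher (2.34, SE 0.40, adjusted p = 0.00271) and 0 of 18 macrophage genes passed in edgeR. The endothelial list had 3 higher and 1 lower of 24, smooth muscle and pericytes 4 and 0 of 16, adipocytes 3 and 1 of 13, Schwann cells and neurons 2 and 0 of 9 (3 and 0 adjusted over the list alone) and lymphocytes 1 and 0 of 9. MYL3 of the ventricular list was higher (2.69, SE 0.51, adjusted p = 0.00479).

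Of the other function lists with JK07, the circadian clock had 4 higher and 1 lower of 18 (7 and 2 adjusted over the list alone; camera adjusted p = 0.779), and unfolded protein and heat shock genes 2 and 1 of 29 (2 and 0 adjusted over the list alone; camera adjusted p = 0.831). Both ways of adjusting, intercalated disc genes had 4 higher and 0 lower of 19, cell cycle genes 4 and 0 of 25, sarcomere genes 3 and 0 of 25, autophagy genes 3 and 0 of 28, oxidative stress genes 2 and 0 of 24, glycolysis genes 2 and 1 of 27, corticosteroid response genes 2 and 3 of 27 and natriuretic and fetal-type genes 1 and 0 of 22.

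Over all genes, 2930 passed in DOCA plus JK07 against DOCA, 2542 higher and 388 lower. Of the higher genes 1594 were at 0 in both DOCA libraries, and leaving out the 1599 with a whole group at 0, 948 were higher and 383 lower. Those at 0 included the genes with the largest fitted rises: QSER1, SLF2, HYCC2, GPAM, a glycerolipid enzyme, and HPS5, of lysosome-related organelles, stood at 10.0 to 13.8 CPM with JK07. The median log2 change of all genes was 0.55 with TMM, 0.44 with RLE and 0.31 with upper quartile factors, which gave 2095 higher and 752 lower genes. Limma on log2(TPM + 1), which differs in measure and test as well, gave 5536 and 90. The median, mean and camera direction differed in sign for the matrix, immediate early, natriuretic, ERBB, corticosteroid, glycolysis, oxidative stress, unfolded protein, autophagy, endothelial, smooth muscle, macrophage, adipocyte, erythrocyte and atrial lists. With quality weights in limma voom 5 genes passed, all called the same way by edgeR and none among the 48 named genes past the threshold: BCL3, a co-factor of NF-kB, lower, CHD9, a chromatin remodeler, higher, and 3 identifiers without a symbol, lower. These 5 fall outside the rule for named genes and were chosen after their values were seen. Thinned to 3.30 M counts 1016 passed (799 higher, 217 lower), and of 1809 genes of at least 100 CPM 399 passed (239 higher, 160 lower). After thinning 19 of the 37 named genes that could be tested kept their call, and COX6C, NDUFS3, COX7B and CAMK2G were not among them.

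The comparison of DOCA plus JK07 with control asked which differences from vehicle-treated hearts were present under both agents. APOE, apolipoprotein E, stood at 10.5 ± 2.26 CPM (SD, n = 3) and 2.98 ± 0.692 (SD, n = 5), a log2 difference of 1.81 (SE 0.26) with adjusted p = 0.977 in edgeR. In DESeq2 its adjusted p was 1.34e-07. The taurine transporter gene SLC6A6 stood at 19.3 ± 18.9 and 1.93 ± 0.441 CPM (3.32, SE 0.63; 2.19 without library 8), with adjusted p = 0.977 in edgeR and 0.000257 in DESeq2. On the lower side were the ribosomal protein genes RPS3A (-0.68, SE 0.15), RPL10A (-1.03, SE 0.24) and RPL9 (-0.98, SE 0.24), each with adjusted p = 1 in edgeR. In DESeq2 their adjusted p was 8.43e-05, 0.00623 and 0.0186.

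In edgeR 0 of 17251 genes passed, and 803 had an unadjusted p under 0.05. DESeq2 called 115 (51 higher, 64 lower) and voom with quality weights 8, all higher. Of these 8 the JK07 means were 0.402 to 10.5 CPM, and APOE alone was above 0 in control. Quality weights on the 2 groups alone gave 0, both TPM models gave 0, and thinning gave 9, all lower. None of the panel genes passed: ERBB4 differed by -0.21 (SE 0.35), NRG1 by 2.07 (SE 0.75; 0.79 without library 9), NPPA by 0.01 (SE 0.19), NPPB by 0.86 (SE 0.62), NR3C2 by 0.17 (SE 0.25), FKBP5 by -0.87 (SE 0.49; -1.49 without library 8), ERBB2 by 0.04 and ERBB3 by 0.43, all with adjusted p = 1.

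Whole lists stood apart in camera, with 0 members past the threshold in edgeR over all genes and, adjusted over the list alone, 1 higher circadian gene. Ribosomal protein genes were lower (median -0.41, adjusted p = 2.49e-17), as were oxidative phosphorylation (-0.37, adjusted p = 8.96e-14), interferon response (-0.43, adjusted p = 7.42e-07) and inflammation and NF-kB (-0.83, adjusted p = 2.08e-05). With an estimated correlation the unadjusted p was 0.0371, 0.0809, 0.118 and 0.0538 in that order. Mitochondrially encoded genes were higher (0.58, adjusted p = 0.000668, p = 0.257 with an estimated correlation), but not without library 10 (adjusted p = 0.738). The tricarboxylic acid cycle was lower (-0.22, adjusted p = 0.000858, p = 0.211 with an estimated correlation; 0.257 without library 9). Macrophage and monocyte genes were lower (-0.61, adjusted p = 0.00285, p = 0.269 with an estimated correlation; 0.0614 without library 5 and 0.210 without library 10). Natriuretic peptides and fetal-type genes were higher (0.38, adjusted p = 0.0454, p = 0.0755 with an estimated correlation), and lost the call without library 2, 3, 4, 5 or 10 (adjusted p = 0.0553, 0.0747, 0.0502, 0.0594 and 0.780). Fry called none of the 36 lists in this comparison. The median, mean and camera direction differed in sign for the ion channel, atrial fibrillation, ERBB, corticosteroid, cell cycle, circadian, fibroblast, adipocyte and atrial lists.

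Of the 4391 genes past the threshold in DOCA against control, 2853 (65.0%) passed in the opposite direction in DOCA plus JK07 against DOCA, and 96.0% had a JK07 mean closer to control than to DOCA. These comparisons share the DOCA libraries. In 10 simulations with the JK07 group equal to DOCA 2.44% passed back (2.05% to 2.90%) and 11.8% were closer to control. With it equal to control 78.6% passed back (76.9% to 79.6%) and 98.2% were closer. These simulations called fewer genes in DOCA against control, on average 3351 and 3438 in that order, against 4391 observed. By count, 2633 to 2762 genes passed back with JK07 equal to control, fewer than the 2853 observed. The observed share lay below that simulation and the observed count above it, so whether the return was complete is undecided. Among genes of at least 100 CPM 375 of 675 passed back, 0 passed in the same direction and 90.2% were closer to control. Of genes lower in DOCA 2490 were higher with JK07, where independent lists would share 501, and of genes higher in DOCA 363 were lower with JK07, where independent lists would share 22.2. Both comparisons use the DOCA libraries with opposite sign, so calls in opposite directions are favoured by design. The numbers for independent lists are therefore no fair baseline. Sharing alone gave 69 to 101 genes back in the simulations with JK07 equal to DOCA, against 2853 observed. That argues against sharing as the whole cause, though the simulations took their spread from all groups. Still, neither these overlaps nor the 0 in the same direction can show an effect of JK07. The DOCA libraries had the fewest counts outside the scaffolds and the most genes at 0, so any libraries without these traits could lie closer to control. The log2 changes of DOCA and of DOCA plus JK07, both against control, correlated across genes at 0.268. Simulated unchanged groups against the same controls gave 0.274 (0.253 to 0.291, 20 simulations), and with the controls split between the comparisons the mean was 0.111 (-0.0426 to 0.189, 20 splits). The covariance was 0.585, against 0.532 simulated (0.487 to 0.570), a difference of 0.0538, and it ran from 0.422 to 0.740 as single libraries were left out. Genes are not independent replicates, so no p-value was computed.

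**Figure D4:**
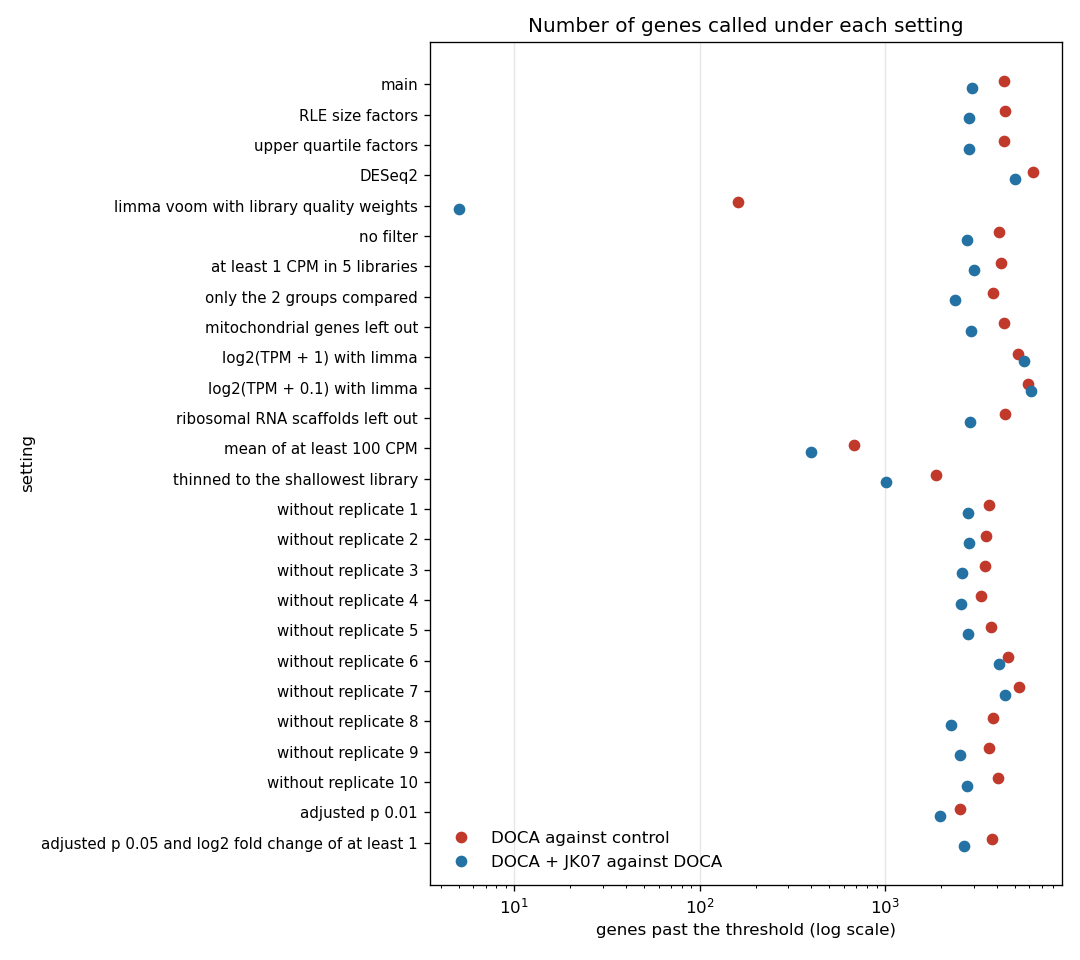
Points give the number of genes past the threshold (logarithmic axis) under each setting for DOCA against control (red) and DOCA plus JK07 against DOCA (blue). The counts run from 161 with quality weights to 6291 with DESeq2 for the former, and from 5 with quality weights to 6084 with limma on log2(TPM + 0.1) for the latter.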

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

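No test of this part was chosen only after its result was seen. Of 98 values of the 5 control libraries (named genes and library measures), 2 stood far from the others, with a gap to the nearest library above 0.71 of the whole range, and chance gives about 1 in 20. NR2F1, a nuclear receptor gene of atrial cells, stood at 0.873 CPM in control library 4, against 1.36 to 1.5 CPM in the other 4 controls (ratio 0.771). DHODH, of pyrimidine synthesis, stood at 8.87 CPM in the same library, against 1.76 to 3.58 CPM in the others (ratio 0.744).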

How the results depend on the processing

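The restriction to genes of at least 100 CPM and the thinning to an equal total count outside the scaffolds, which left library 6 with more genes at 0 (39.7%), were tests chosen only after the results were seen. Where no reason is given the cause was not tested. DOCA against control (4391 genes) gave 161 with quality weights and 1881 after thinning. At least 100 CPM gave 675, with 1809 genes tested, and an adjusted p of 0.01 gave 2521, by construction. Leaving out 1 library gave 3307 to 5286. DOCA plus JK07 against DOCA (2930) gave 5045 in DESeq2, 5 with quality weights, 5626 and 6084 on log2(TPM + 1) and log2(TPM + 0.1), 399 at 100 CPM and 1016 after thinning, and 2277 to 4455 without 1 library, the highest without library 7. DOCA plus JK07 against control (0 in edgeR, 803 at an unadjusted p under 0.05) gave 115 in DESeq2, 8 with quality weights and 9 after thinning, and 0 to 0 without 1 library. All other scalings, filters and models kept these counts within 1.5 times, which compares totals and not the genes called. In DOCA against control RLE shared 4208 of its 4415 genes with the main test in the same direction, and log2(TPM + 1) shared 3289 of 5191. In DOCA plus JK07 against DOCA the fit of only the 2 groups shared 1878 of 2367, with 112 lower genes against 388. Camera called 6 lists in DOCA against control, 0 with an estimated correlation, 0 at 100 CPM, where 26 lists could be tested, 6 in fry and 5 to 7 without 1 library. Fry shared only 3 of them (tricarboxylic acid cycle, mitochondrially encoded and ribosomal protein genes) and called oxidative stress, ventricular and histone genes instead of oxidative phosphorylation (adjusted p = 0.0901), interferon (0.121) and matrix genes (0.686). For DOCA plus JK07 against DOCA it called 4, then 0, 0, 5 in fry and 2 to 9 (9 without library 6, 7 without 9, 2 without 7 or 10), and against control 8, then 0, 4, 0 in fry and 7 to 12. Of the 4 in DOCA plus JK07 against DOCA, fry shared only the mitochondrially encoded genes (adjusted p = 0.0349), not inflammation (0.318), matrix (0.904) or immediate early genes (0.899); its others were transcription factors, oxidative stress, ventricular and histone genes. The extracellular matrix list of DOCA plus JK07 against DOCA turned to higher at 100 CPM (adjusted p = 0.947) and without library 7 (0.851), with 1.17e-05 to 0.851 over libraries left out. Without library 7, ERBB3 turned to -10.45 in DOCA against control (adjusted p = 0.00290) and to 10.88 in DOCA plus JK07 against DOCA (adjusted p = 0.00275); library 6 lists it at 0, so no fold can be read and the call follows from that 0. Without library 6 they were 1.96 and -1.53. The correlation of fold changes (0.268) was 0.111 with split controls, where shared controls no longer add to it, and 0.168 to 0.317 without 1 library (0.317 without 5, 0.197 without 6, 0.168 without 10). Genes changed back (2853) were 4774 in DESeq2, 375 at 100 CPM, 978 after thinning and 2244 to 4323 without 1 library (4323 without 7). Over the planned and added settings other than leaving out libraries, named genes kept direction and side of the threshold in 698 values of DOCA against control, 582 of DOCA plus JK07 against DOCA and 180 of DOCA plus JK07 against control, and lost the threshold in 77, 81 and 0. They gained it in 2, 4 and 7. With library quality weights none of the 48 named genes of DOCA plus JK07 against DOCA kept its call. No paired analysis was run because the labels gave no pairing, and whether groups shared a source or a batch is unknown.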

Other observations

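The tests of a general fall of transcripts and of carried-over cytoplasmic RNA were chosen only after the results were seen, as were both further versions of the trend test and the set of 1780 genes used for neighbouring gene number. The readings of the general fall, carried-over RNA, trend and gene count split tests were changed to undecided after their results were seen. The genes named in the next paragraphs were chosen after their values were seen. In DOCA against control, glycolysis split: 2 genes rose and 5 fell of 27 (3 and 5 adjusted over the list alone; camera adjusted p = 0.727). ENO1, the ubiquitous enolase, rose from 17.5 to 42.1 CPM (log2 change 1.27, adjusted p = 0.00315) while ENO3, the muscle enolase, fell from 16.8 to 4.78 CPM (-1.81, adjusted p = 0.00773). Of 28 autophagy, proteasome and atrophy genes 2 rose and 4 fell (camera adjusted p = 0.831), with BNIP3L, a mitophagy receptor, at -1.82 (adjusted p = 0.000491). Of 24 genes of oxidative stress defence 4 fell (2 adjusted over the list alone; camera adjusted p = 0.831; fry adjusted p = 0.0349), with NFE2L2, the NRF2 gene, at -1.24 (adjusted p = 0.00267). Of 19 intercalated disc genes 3 fell (camera adjusted p = 0.934), with CTNNB1, beta-catenin, at -0.92 (adjusted p = 0.00563). Of 25 cell cycle genes 6 fell (camera adjusted p = 0.870), and 18 of the 25 had a DOCA library at 0. For autophagy, intercalated disc and cell cycle genes the counts adjusted over the list alone were the same.

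Some genes moved in the same sense in both DOCA libraries and back with JK07. BCL3 stood at 2.27 CPM in control, 10.9 in DOCA and 1.63 with JK07, and RELB, a subunit of NF-kB, at 2.33, 7.89 and 1.79 CPM. CHD9 stood at 47.9, 8.40 and 41.4 CPM, MYOZ2 at 70.3, 14.1 and 87.2 CPM, and TIMP1 at 2.76, 14.0 and 2.32 CPM. In DOCA plus JK07 against DOCA, BCL3 changed by -2.74 (adjusted p = 7.05e-05), RELB by -2.14 (adjusted p = 0.00948) and CHD9 by 2.30 (adjusted p = 0.000150). MYOZ2 changed by 2.63 (adjusted p = 0.000511) and TIMP1 by -2.59 (adjusted p = 0.00381). Leaving out any 1 control or JK07 library ended none of these calls. Without library 6 or 7 a lone DOCA library remained and its spread was assumed, so those fits cannot show that a call is stable. Both comparisons use the same DOCA libraries, which favours moves back. MYH7B, a slow myosin gene, depended on library 6: it changed by 3.33 in DOCA against control (adjusted p = 0.00378), by 0.93 without library 6 (adjusted p = 0.115) and by 4.18 without library 7.

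Most genes called in DOCA against control were lower. Low depth with the coverage minimum is argued against as the whole cause, since thinned controls had at most 21.7% of genes at 0 against 24.5% and 39.7% in the DOCA libraries, though thinning brought the controls much closer to library 7, so depth stays open as part of the cause. A general fall of transcripts stays open: among genes of at least 100 CPM 52.3% of those called were lower, but that fit centres these genes on themselves, and with TMM over all genes 390 of 634 (61.5%) were lower. Uneven recovery by base composition may contribute: with neighbouring genes within 1 Mb as a stand-in, the Spearman rho of the log2 ratio across genes was 0.231 and 0.253 in the DOCA libraries and at most 0.178 in the other 8. An effect of DOCA stays open, untested, because both DOCA libraries have low depth and many genes at 0.

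Genes of oxidative phosphorylation and ribosomal proteins were lower in DOCA, with a median of -1.05 over 93 genes that lay below all of 10000 random lists matched on expression. That rank is no separate support, since camera had already called both lists lower in this comparison. Random lists were drawn gene by gene and do not carry the correlation within a gene family, so such a rank can look more extreme than it is. After a trend with gene span and neighbouring genes was removed, the median lay at percentile 4.38. By the rule set in advance, a percentile of at least 2.5 pointed to the trend as the cause. That median was 1.61, with random lists at 1.57 to 2.20, so the values left by this fit lay well above 0. The fit included genes listed at 0 in a whole group, whose fold changes were not read as sizes. A robust trend put it at 40.8, so both fits over the 93 genes lay on the same side of that bound. Among 19 genes of at least 100 CPM it lay at 0.02 after least squares removal and 1.27 before. The result turned where the genes fitted and tested were changed together. The trend and a change of these genes therefore cannot be told apart. Less cytoplasmic RNA carried over into the DOCA nuclei could lower these genes, and the fall of 13 of 13 mitochondrially encoded genes goes with that. The sarcomere list, rich in cytoplasmic messengers, lay at percentile 22.3, but its members went both ways (12 above and 13 below 0), so this does not decide, and an effect of DOCA stays open, untested.

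For DOCA plus JK07 against control edgeR called 0 genes (803 at an unadjusted p under 0.05, 115 in DESeq2), so that 56 of the 56 splits of the 8 libraries into 5 and 3 reached that count by construction, which decides nothing. The highest other split gave 17, and 10 other splits gave at least 1. For gene lists 33 of the 56 splits gave at least the real 8, with a median of 8 and a highest value of 18 in the others. Chance can thus not be excluded for the number of lists, and a difference of the groups in these lists stays open.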
